A study of Homo sapiens with 17 samples.

How the data were processed

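RNA was taken from 17 ZR-75-1 xenograft tumours after 5 days of vehicle (n = 4), DHT (n = 5), enobosarm (n = 4) or enzalutamide (n = 4). Per the labels' protocols, RNA was extracted with RNeasy kits, libraries were made with a TruSeq Stranded mRNA kit and reads of 125 bp were sequenced from both ends on a HiSeq 2500. The submitters' processing notes name bcl2fastq, FastQC 0.11.4, cutadapt 1.9.1, STAR 2.4.2a, RSEM 1.2.21, limma and the genome build hg38, with no order or role for each. The annotation release, the strand setting of the counting and any removal of mouse reads are not given in the sources used here. Values of antisense and overlapping genes are therefore uncertain, and reads from mouse cells of the tumour may be counted in human genes of similar sequence.

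The expected counts were deposited by the authors per gene and library as RSEM wrote them, with no normalization, for 58688 genes, of which 32102 had any count. The 92 rows for spike-in controls held 0 counts in every library. The TPM values were deposited by the authors for the same libraries, as RSEM computes them. For DHT against vehicle the authors deposited a table of log2 fold changes and average log2 expression, and with them a p-value and an adjusted p-value per gene, in columns named as limma writes them. That table lists only genes with an adjusted p under 0.05, and the design behind it is not given in the sources used here. Deposited FPKM files, and TPM without genes at 0, hold the same libraries in another form and were not used here.

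Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the 4 groups (minimum count 10, minimum total 15), which left 16780 genes holding 99.89% of the counts. Libraries were scaled with TMM factors, and all 17 libraries entered 1 quasi-likelihood fit with a mean per group, robust dispersions, 13 residual degrees of freedom and no covariate. The common biological coefficient of variation was 20.1%. The 6 contrasts between groups were tested with glmQLFTest, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its contrast. Log2 CPM used a prior count of 2, and CPM values are given as mean ± SD over the libraries of a group. Log2 fold changes are given with a standard error (SE), taken as their absolute value over the square root of the test's F statistic. The 95% intervals of log2 fold changes use the same SE, which is approximate for genes with few counts. A fold against a group with 0 counts is a lower bound against a floor of 3 counts over the group, and with 1 to 3 counts the 95% counting interval of the ratio is given. These intervals and floors cover counting error only, since counts were summed over the tumours of a group and the spread between tumours is left out. The reads carry no molecular identifiers, so duplicate reads could not be told apart either.

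The comparisons, tests, gene lists and naming rule were fixed before the data were examined. Of 27 lists, 25 had at least 5 tested members and were tested with camera (limma 3.58.1, preset correlation 0.01), adjusted by Benjamini-Hochberg over 150 tests of 25 lists in 6 contrasts. Of these, 57 passed with the preset correlation, 18 with a correlation estimated per list and 35 with fry, which asks only whether the genes of a list move one way. The list means are means of log2 fold changes, and list calls with 1 library left out or with only 2 groups are adjusted over the lists run in that setting. Skeletal muscle markers (4 tested members) and red cell genes (0 tested members) were too few to test.

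The genes named in each comparison with vehicle are up to 10 with the highest and up to 10 with the lowest log2 fold change among those called, with a mean of at least 1 CPM in the higher group and no overlap between the libraries of the groups. Where none passed in a direction, the 3 with the smallest p are named as not passing. For DHT against enobosarm the number is 5 per direction. ESR1, PGR, GREB1, FKBP5, SEC14L2 and MKI67 are given in every comparison, and up to 4 members of each list with the smallest p, of which mainly those called without any 1 library are printed. Genes without a symbol and pseudogenes were counted but not named, and the results of a few genes that the rule selects are not reported here. A few genes outside the rule are marked as chosen after their values were seen. Gene positions are from GENCODE 29 on GRCh38, the assembly that hg38 denotes, and 16567 of the tested gene identifiers were found in it.

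Because comparisons with vehicle share the same libraries, correlations of fold changes were set beside 100 simulations of unchanged groups against those libraries and 6 arrangements of the vehicle libraries split 2 against 2. The authors' deposited table was matched by unique gene symbol. The gene test was tested on simulated data, with 200 of 16780 genes changed, drawn from those with a mean of at least 1 CPM. The recoveries therefore do not cover genes with lower counts. Counts were drawn independently per gene with the fitted dispersions, so no simulated tumour deviated in many genes at once. For DHT against vehicle it recovered 37.3%, 79.1% and 95.5% of genes changed 1.5-fold, 2-fold and 4-fold, with 8 false among 149 calls. For enobosarm against vehicle it recovered 16.4%, 77.6% and 95.5% (4 false of 130), for enzalutamide against vehicle 31.3%, 62.7% and 97% (7 of 134) and for DHT against enobosarm 25.4%, 67.2% and 92.4% (9 of 132).

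The alternatives tried were DESeq2 1.42.0, limma-voom, limma on log2(TPM + 1), median-of-ratios factors, no filter on low counts, the authors' filtered genes, only the libraries of the groups compared, the replicate number as a block, the library number as a covariate, camera with an estimated correlation, fry, and leaving out each library in turn. Thinning every library to the smallest total was added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.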

Results

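Gene expression was measured by RNA-seq in 17 tumours grown from ZR-75-1, a human breast cancer cell line that expresses the estrogen receptor. For each tumour, 5000000 cells were placed in the mammary fat pad of an athymic nude mouse carrying an estradiol pellet. Treatment started at a tumour volume of about 200 mm3 and lasted 5 days. The androgen dihydrotestosterone (DHT) was given from an implanted pellet to 5 tumours, at a dose not given in the sources used here. Enobosarm, a non-steroidal compound with androgenic action, was given by mouth at 10 mg/kg/day to 4 tumours, and enzalutamide, an antagonist of androgen action, by mouth at 20 mg/kg/day to 4. The other 4 tumours received vehicle. Total gene counts averaged 19257530 ± 3538183 (SD, n = 4) in vehicle and 16779190 ± 5274248 (n = 5) in DHT libraries. They averaged 18801946 ± 3167089 (n = 4) in enobosarm and 13510134 ± 1940677 (n = 4) in enzalutamide libraries, and ranged from 8495428 in DHT 1 to 23949928 in Vehicle 4. Mice were assigned to the groups at random, and the labels number the tumours of a group without saying whether each came from a separate mouse, so p-values measure only the spread between these tumours. On the first principal component of log2 CPM (36.8% of the variance) the DHT libraries scored 39.7 to 58.5, the enobosarm libraries 7.4 to 30.1, the vehicle libraries -48.5 to -33.4 and the enzalutamide libraries -52.6 to -23.1.

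The series asks how androgen signalling acts in estrogen receptor-positive breast cancer, and the first comparison shows the change under DHT in tumours supplied with estradiol. DHT raised androgen-response genes and lowered estrogen-response genes. The transcript of the estrogen receptor, ESR1, fell from 186 ± 25.7 CPM (SD, n = 4) in vehicle to 30.8 ± 6.64 CPM (n = 5), 6.03-fold lower (log2 fold change -2.59 ± 0.18 SE, edgeR adjusted p = 4.45e-08). FKBP5, a co-chaperone of steroid receptors induced by androgens, rose 5.45-fold from 122 ± 30.9 to 667 ± 120 CPM (2.45 ± 0.20, edgeR adjusted p = 2.03e-07).

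PGR, which encodes the progesterone receptor and is induced by the estrogen receptor, was 12.2-fold lower under DHT, at 19.7 ± 9.15 against 246 ± 36.5 CPM (-3.61 ± 0.45, edgeR adjusted p = 3.42e-05). GREB1, an estrogen receptor cofactor and target, was 3.58-fold lower (133 ± 61.6 against 475 ± 142 CPM, edgeR adjusted p = 0.00114). SEC14L2, a lipid-binding protein in the androgen-response list, was 4.36-fold higher (67.6 ± 4.72 against 15.5 ± 3.95 CPM, edgeR adjusted p = 2.33e-06). Of 39 tested androgen-response genes 27 rose and 2 fell (27 and 3 adjusted over the list alone), with a mean log2 fold change of 1.54 (camera adjusted p = 2.3e-20). The leading members were RAB3B (4.81 ± 0.30), SORD (2.29 ± 0.18), CYP4F8 (7.47 ± 0.52) and FKBP5. Of 52 tested estrogen-response genes 41 fell and 1 rose (42 and 2 adjusted over the list alone), with a mean of -1.75 (camera adjusted p = 1.8e-27, and adjusted p = 0.048 with an estimated correlation). MYB (-2.10 ± 0.14), RERG (-2.42 ± 0.17), ANXA9 (-2.76 ± 0.24) and OLFM1 (-2.19 ± 0.21) had the smallest p-values in that list. In GRCh38, ESR1 (ENSG00000091831) lies on chromosome 6 from 151656691 to 152129619. PGR (ENSG00000082175) lies on chromosome 11 from 101029624 to 101130524 and GREB1 (ENSG00000196208) on 2 from 11482341 to 11642788. FKBP5 (ENSG00000096060) lies on chromosome 6 from 35573585 to 35728583 and SEC14L2 (ENSG00000100003) on 22 from 30396857 to 30425317.

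**Figure D1:**
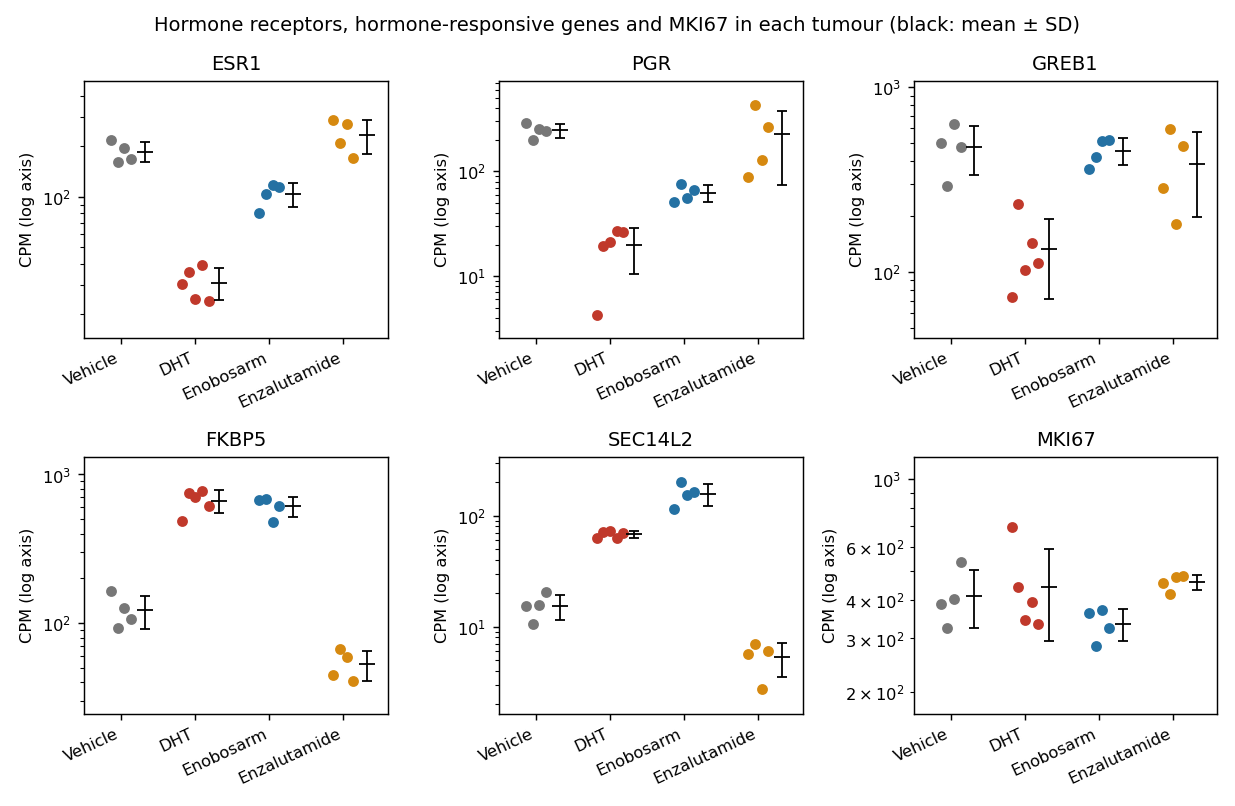
TMM-normalised CPM on a log axis for ESR1, PGR, GREB1, FKBP5, SEC14L2 and MKI67 in each tumour, with 1 point per tumour and the mean ± SD of each group in black (vehicle, enobosarm and enzalutamide n = 4, DHT n = 5). Mean ESR1 was 186 CPM in vehicle, 30.8 under DHT, 104 under enobosarm and 234 under enzalutamide, and mean FKBP5 122, 667, 613 and 53.1 CPM in the same order.

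The genes with the highest fold changes under DHT, among those with every DHT library above every vehicle library, were mostly enzymes of steroid, lipid and drug metabolism. SULT1C3, a sulfotransferase, had 0 counts in the vehicle libraries and was at least 117-fold higher under DHT, against a floor of 3 counts over the group. PNLIPRP3, a pancreatic lipase-related protein, and UGT2B28, UGT2B11 and the collagen-binding integrin ITGA11 had 1 to 3 counts over the vehicle libraries. Their DHT-to-vehicle ratios had 95% counting intervals of 175 to 5250, 139 to 4170, 154 to 2190 and 20.0 to 4520. CYP4F8, a fatty acid hydroxylase (7.47 ± 0.52), PGC, pepsinogen C (7.01 ± 0.99), HPGD, which degrades prostaglandins (5.99 ± 0.70), and AKR1C2, which inactivates DHT (5.78 ± 0.72), were also among them. Counts of UGT2B, UGT1A, AKR1C, SULT1C and CYP4F genes are uncertain wherever they are named, because RSEM divides reads among near-identical family members. Among the 10 lowest genes, CST9 had 0 counts under DHT and was at least 30.2-fold lower, and CCDC3 had 1 to 3 counts under DHT, with a 95% counting interval of its vehicle-to-DHT ratio of 20.0 to 614. The orphan receptor GPR139 (-6.14 ± 0.55), SEZ6L (-6.03 ± 1.03), SERPINA4 (-5.61 ± 0.68) and AMPH (-5.51 ± 0.86) followed. OLFM4 (-5.49 ± 0.72), GSG1L (-5.49 ± 0.99), the protease gene TMPRSS3 (-5.48 ± 0.76) and the chemokine CXCL12 (-5.39 ± 0.70) were the others. edgeR adjusted p for these genes ranged from 4.45e-08 for UGT2B11 to 0.00067 for GSG1L, and each passed without any 1 library of the comparison.

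Genes of steroid inactivation and synthesis rose under DHT, 11 of 17 higher and 2 lower (11 and 2 adjusted over the list alone). AKR1C3, which interconverts weak and potent androgens, had a log2 fold change of 4.22 ± 0.30 and HSD11B2, which inactivates cortisol, of 2.23 ± 0.24. The list mean was 2.31, or 2.17 with the 1 member at 0 counts in a group set at its bound, and its median 0.86 (camera adjusted p = 2.0e-10, and adjusted p = 0.00099 with an estimated correlation). In cholesterol synthesis 13 of 22 genes were higher and 0 lower by edgeR (15 and 0 adjusted over the list alone). HMGCS1 (0.88 ± 0.09), SC5D (1.30 ± 0.15) and MVD (0.86 ± 0.19) were among them, with camera adjusted p = 1.4e-06 but adjusted p = 0.33 with an estimated correlation. In fatty acid synthesis 10 of 24 were higher and 3 lower (11 and 3 adjusted over the list alone), led by ACACA (1.59 ± 0.13), the first committed enzyme, and ELOVL5 (1.59 ± 0.15), with camera adjusted p = 0.00073 and adjusted p = 0.14 with an estimated correlation. In fatty acid oxidation 8 of 19 were higher (8 adjusted over the list alone), including ECI2 (1.76 ± 0.15) and ETFDH (0.78 ± 0.11), with camera adjusted p = 0.0016 and adjusted p = 0.27 with an estimated correlation. Of 14 apocrine and milk secretory genes 8 were higher (8 adjusted over the list alone), including AZGP1 (1.46 ± 0.15), ACSM1 (2.50 ± 0.32) and PIP (2.28 ± 0.28), with camera adjusted p = 1.6e-05 and adjusted p = 0.14 with an estimated correlation. AZGP1 and PIP are also members of the androgen-response list.

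On average, proliferation genes changed little under DHT over all 5 tumours, but the tumours differed in direction. DHT 1 scored 0.569 on S phase and 0.671 on G2/M genes (mean log2 CPM, centred per gene). Vehicle libraries scored 0.06 to 0.251 and -0.038 to 0.385, and the other DHT libraries -0.218 to -0.14 and -0.349 to -0.187. DHT 1 thus lay above every vehicle library and the other DHT libraries below every one. MKI67, a marker of cycling cells, was at 442 ± 148 CPM under DHT and 413 ± 88.3 in vehicle (0.10 ± 0.18, edgeR adjusted p = 0.756). Of 50 S phase genes 3 passed as lower, among them CDT1 (-0.67 ± 0.18), and 0 adjusted over the list alone. The S phase mean was -0.11 (camera adjusted p = 0.27), and without DHT 1 it was -0.28 (camera adjusted p = 8.8e-05). Of 48 G2/M genes edgeR called 0 (also 0 adjusted over the list alone), with 11 lower at an unadjusted p under 0.05, DESeq2 calling 0 and limma-voom 8 lower. The G2/M mean was -0.20 (camera adjusted p = 0.047, and adjusted p = 0.97 with an estimated correlation). It was -0.43 without DHT 1. It missed the threshold at -0.12 without Vehicle 4, -0.20 without Vehicle 2, and -0.16, -0.13, -0.14 and -0.15 without DHT 2, 3, 4 and 5 (adjusted p from 0.068 to 0.28). MYC (-1.75 ± 0.18), also in the estrogen-response list, and FBL (-0.58 ± 0.14), an rRNA methyltransferase, were among 6 of 29 ribosome biogenesis and MYC target genes that fell (4 adjusted over the list alone). The ribosome biogenesis and MYC target list had camera adjusted p = 0.0013 and adjusted p = 0.85 with an estimated correlation. DHT 1 scored 0.169 on that list, within the vehicle libraries (0.075 to 0.267), and the other DHT libraries -0.325 to -0.071.

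Receptors, growth factor and developmental genes moved both ways under DHT. Of 28 luminal receptors and cofactors 9 rose and 4 fell (11 and 4 adjusted over the list alone), with ESR1 and the luminal transcription factor GATA3 (-1.45 ± 0.18) lower and TFAP2A (0.76 ± 0.09) higher. The list mean was -0.06 and its median 0.20, opposite in sign (camera adjusted p = 0.52). In the insulin-like growth factor and receptor tyrosine kinase list 7 of 32 rose and 8 fell (7 and 9 adjusted over the list alone, camera adjusted p = 0.39), with IGF1R (-1.58 ± 0.22), IRS1 (-1.54 ± 0.27) and IGFBP4 (-2.10 ± 0.27) lower. IRS1 and IGFBP4 are also members of the estrogen-response list. In the WNT and developmental list 3 of 19 rose and 6 fell (4 and 8 adjusted over the list alone, camera adjusted p = 0.23), with the Notch ligand JAG1 at -2.72 ± 0.33 and WNT7B at 1.33 ± 0.25. Of 28 immediate early and heat-shock genes 10 rose and 3 fell (11 and 3 adjusted over the list alone, camera adjusted p = 0.061), and EGR3, also in the estrogen-response list, was at -3.95 ± 0.59. Without DHT 3, 4 or 5, or Vehicle 2, that list passed, with means of 0.12, 0.14, 0.11 and 0.26 against 0.08 with every library. In the unfolded protein response list 5 of 26 rose and 0 fell (5 and 0 adjusted over the list alone, camera adjusted p = 0.16), and without DHT 5 its mean of 0.15 was 0.20 (camera adjusted p = 0.035).

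The remaining lists missed the camera threshold under DHT. There were 2 higher and 3 lower of 27 cell cycle inhibitors and DNA damage response genes (2 and 3 adjusted over the list alone), with BTG2 at -0.71 ± 0.15. Interferon-stimulated genes held 1 higher of 24 (0 adjusted over the list alone) and antigen presentation genes 1 higher and 1 lower of 15 (0 and 1 adjusted over the list alone), the latter with a mean of -0.005 and a median of 0.08. There were 2 higher and 1 lower of 30 hypoxia genes (1 and 0 adjusted over the list alone), with the glucose transporter SLC2A3 at 2.37 ± 0.45, and 1 higher of 15 mitochondrially encoded genes (1 adjusted over the list alone). Genes listed as markers of other cell types were sparse, and no step that removed mouse reads is given in the sources used here. Fibroblast markers held 2 higher and 1 lower of 14 (2 and 1 adjusted over the list alone), with a mean of 0.18 and a median of -0.15. Endothelial and pericyte markers held 1 higher, VWF at 3.55 ± 0.32, and 3 lower, with RGS5 at -2.87 ± 0.54, of 6 (1 and 3 adjusted over the list alone). Basal, myoepithelial and epidermal markers held 3 higher of 10 (4 higher and 1 lower adjusted over the list alone), with IVL at 3.47 ± 0.55, and adipocyte markers 1 higher of 6 (1 adjusted over the list alone). Of 6 leukocyte markers edgeR called 0, with 2 higher at an unadjusted p under 0.05, DESeq2 calling 1 and limma-voom 0. Camera adjusted p in these lists ranged from 0.14 for the mitochondrially encoded genes to 1 for the fibroblast markers.

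In all, edgeR called 4202 of 16780 genes between DHT and vehicle, 2084 higher and 2118 lower, of which 681 and 927 changed at least 2-fold. On log2(TPM + 1), limma called 1221 higher and 1978 lower. The authors' deposited table of this comparison lists 3393 genes at an adjusted p under 0.05, 1731 higher and 1662 lower under DHT. Of the 2879 that matched a unique symbol, all 2879 had the same sign and 2799 (97.2%) were also called here, with a Pearson correlation of log2 fold changes across those genes of 0.995. The authors' deposited table gives ESR1 at -2.60, PGR at -3.87 and FKBP5 at 2.46. Both sets of values come from the same libraries.

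Enobosarm raised androgen-response genes by nearly as much as DHT did, and lowered the estrogen receptor less. FKBP5 was 5.01-fold higher than in vehicle, at 613 ± 95.7 CPM (SD, n = 4; 2.32 ± 0.20, edgeR adjusted p = 1.18e-06), and SEC14L2 10.1-fold higher, at 158 ± 34.7 CPM (3.34 ± 0.23, edgeR adjusted p = 1.08e-07). ESR1 was 1.78-fold lower, at 104 ± 16.8 CPM (-0.83 ± 0.18, edgeR adjusted p = 0.00604), and PGR 3.94-fold lower, at 62.4 ± 11.3 CPM (-1.98 ± 0.46, edgeR adjusted p = 0.011). GREB1 (454 ± 75.9 CPM, -0.07 ± 0.36, edgeR adjusted p = 0.934) and MKI67 (335 ± 40.2 CPM, -0.30 ± 0.19, edgeR adjusted p = 0.356) did not pass.

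The highest genes under enobosarm shared 8 of 10 names with those under DHT. SULT1C3, UGT1A3 and UGT1A5 had 0 counts in the vehicle libraries and were at least 97.8-fold, 48.6-fold and 41.6-fold higher, and UGT1A genes share all but their first exons. PNLIPRP3, ITGA11, UGT2B28 and UGT2B11, with 1 to 3 counts over the vehicle libraries, had ratios with 95% counting intervals of 78.0 to 2340, 25.1 to 5670, 27.0 to 825 and 27.8 to 401. CYP4F8 (8.41 ± 0.53), PGC (6.86 ± 1.00) and AKR1C2 (5.63 ± 0.73) were the others. Among the lowest were the muscle ring-finger gene TRIM55 (-4.09 ± 0.92), CCDC3 (-4.03 ± 0.66), OLFM4 (-3.83 ± 0.70), GSG1L (-3.57 ± 0.86), AMZ1 (-3.56 ± 0.79), PYDC1 (-3.56 ± 0.74), ABI3BP (-3.56 ± 0.40), the amino acid transporter SLC6A15 (-3.14 ± 0.57) and TBX1 (-3.04 ± 0.79). edgeR adjusted p for these genes ranged from 1.24e-07 for CYP4F8 to 0.0193 for TBX1. GSG1L missed the threshold without Vehicle 4 (-1.93, adjusted p = 0.088) or Enobosarm 1, TBX1 without Vehicle 4 (-1.84, adjusted p = 0.12), Enobosarm 1 or Enobosarm 3, and PYDC1 was at -5.52 without Enobosarm 3.

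Of 39 androgen-response genes 22 rose and 2 fell under enobosarm (25 and 4 adjusted over the list alone), with a mean of 1.38 (camera adjusted p = 5.0e-24, and adjusted p = 0.00072 with an estimated correlation). They were led by SEC14L2, CYP4F8, RAB3B (4.18 ± 0.30) and SORD (2.12 ± 0.18). Steroid inactivation and synthesis genes had 8 of 17 higher and 0 lower by edgeR (8 and 1 adjusted over the list alone) and a mean of 1.81, or 1.67 with the 1 member at 0 counts in a group set at its bound (camera adjusted p = 2.4e-08, and adjusted p = 0.0019 with an estimated correlation). AKR1C3 there was at 4.98 ± 0.31. Apocrine and milk secretory genes had 6 of 14 higher (7 adjusted over the list alone), with AZGP1 (1.51 ± 0.16), PIP (2.23 ± 0.28) and APOD (2.19 ± 0.29), and a mean of 0.94 (camera adjusted p = 4.3e-08, and adjusted p = 0.048 with an estimated correlation). Cholesterol synthesis had 11 of 22 higher (15 adjusted over the list alone), among them DHCR7 (1.08 ± 0.22) and SC5D (0.79 ± 0.16), with camera adjusted p = 1.5e-07 and adjusted p = 0.27 with an estimated correlation. Fatty acid synthesis had 7 of 24 higher and 2 lower (9 and 3 adjusted over the list alone), with ELOVL5 at 1.82 ± 0.16 and ACSL1 at 2.51 ± 0.36, camera adjusted p = 0.00012 and adjusted p = 0.083 with an estimated correlation. Fatty acid oxidation had 5 of 19 higher (7 adjusted over the list alone), led by ECI2 (1.80 ± 0.15), with a mean of 0.19, camera adjusted p = 0.035 and adjusted p = 0.61 with an estimated correlation. Its mean was 0.15 without Vehicle 3, 0.16 without Enobosarm 2 and 0.15 without Enobosarm 3, and then missed the threshold.

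Estrogen-response genes fell in smaller number under enobosarm, 10 of 52 lower and 1 higher (10 and 1 adjusted over the list alone), with a mean of -0.41 (camera adjusted p = 0.0028, and adjusted p = 0.86 with an estimated correlation). RERG (-1.16 ± 0.17), ANXA9 (-1.57 ± 0.24) and MYB (-0.89 ± 0.15) had the smallest p-values. Cell-cycle genes were lower on average. Of 50 S phase genes 3 fell and 0 did so adjusted over the list alone (mean -0.31, camera adjusted p = 7.1e-06, and adjusted p = 0.86 with an estimated correlation). Of 48 G2/M genes edgeR called 0 (0 adjusted over the list alone), with 20 lower at an unadjusted p under 0.05, DESeq2 calling 3 lower and limma-voom 1 (mean -0.38, camera adjusted p = 1.3e-06, and adjusted p = 0.86 with an estimated correlation). Of 29 ribosome biogenesis and MYC target genes 3 fell (3 adjusted over the list alone), with ODC1, the first enzyme of polyamine synthesis, at -1.59 ± 0.31 and MYC at -0.77 ± 0.19 (camera adjusted p = 0.0017, and adjusted p = 0.86 with an estimated correlation).

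The unfolded protein response list had 5 of 26 higher under enobosarm (6 adjusted over the list alone), with SEL1L at 0.46 ± 0.10 (mean 0.20, camera adjusted p = 0.0057, and adjusted p = 0.86 with an estimated correlation), and its mean was 0.11 without Enobosarm 3 (adjusted p = 0.079). Immediate early and heat-shock genes had 4 of 28 higher and 1 lower (6 and 1 adjusted over the list alone), with NR4A1 at 1.34 ± 0.25 and HSPH1 at 0.86 ± 0.17 (mean 0.15, camera adjusted p = 0.035, and adjusted p = 0.88 with an estimated correlation). That mean was 0.03 without Enobosarm 3, 0.12 without Enobosarm 1, 0.08 without Vehicle 1 and 0.13 without Vehicle 3, none of which passed, 0.33 without Vehicle 2 and 0.23 without Enobosarm 2. Mitochondrially encoded genes, 0 of 15 called by edgeR, DESeq2 or limma-voom and 2 at an unadjusted p under 0.05, had a mean of 0.22 (camera adjusted p = 0.049, and adjusted p = 0.88 with an estimated correlation). They missed the threshold at 0.18 without Enobosarm 1, 0.19 without Enobosarm 4, 0.22 without Vehicle 2 and 0.19 without Vehicle 3.

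The camera test did not pass under enobosarm for luminal receptors and cofactors (3 higher and 3 lower of 28, 9 and 3 adjusted over the list alone), with CDH1 at 0.60 ± 0.12, or for the insulin-like growth factor and receptor tyrosine kinase list (2 and 1 of 32, 2 and 1 adjusted over the list alone), with SPRED2 at 1.02 ± 0.23. Neither did the WNT and developmental list pass (3 and 3 of 19, 3 and 3 adjusted over the list alone), with WNT4 at -2.58 ± 0.55 and SP5 at 1.67 ± 0.38. The same held for cell cycle inhibitors and DNA damage response genes (1 lower of 27, 1 adjusted over the list alone) and for interferon-stimulated genes (1 higher of 24, 1 adjusted over the list alone), with PARP9 at 0.72 ± 0.16. Hypoxia genes missed the threshold too (1 higher and 1 lower of 30, 1 and 1 adjusted over the list alone), with SLC2A3 at 2.06 ± 0.46. Without Vehicle 1 the hypoxia mean of -0.34 was -0.53 (camera adjusted p = 0.037). Fibroblast markers had 1 of 14 higher (1 adjusted over the list alone), COL6A3 at 1.53 ± 0.32, and endothelial and pericyte markers 1 of 6 higher (1 higher and 1 lower adjusted over the list alone), VWF at 2.87 ± 0.32. Endothelial and pericyte, adipocyte, and basal, myoepithelial and epidermal markers had means of -0.24, 0.02 and -0.11 and medians of -0.59, -0.14 and -0.41. Of the antigen presentation, leukocyte, adipocyte and basal, myoepithelial and epidermal markers, edgeR called 0 of 15, 0 of 6, 0 of 6 and 0 of 10, with 6, 0, 1 and 3 at an unadjusted p under 0.05. DESeq2 called 1 antigen presentation gene and 1 basal, myoepithelial and epidermal marker, and limma-voom 1 of the latter.

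Between enobosarm and vehicle edgeR called 1769 genes, 1027 higher and 742 lower, of which 404 and 324 changed at least 2-fold. On log2(TPM + 1), limma called 536 higher and 786 lower. Without Vehicle 4 edgeR called 1073 genes and without Enobosarm 1 it called 1081.

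Few genes were called under enzalutamide, and RGS2, SEC14L2 and FKBP5, which rose under both agonists, fell. RGS2, a regulator of G protein signalling, was 4.61-fold lower than in vehicle (-2.20 ± 0.28, edgeR adjusted p = 0.00535). SEC14L2 was 2.92-fold lower, at 5.37 ± 1.83 CPM (SD, n = 4) against 15.5 ± 3.95 (-1.54 ± 0.24), FKBP5 2.30-fold lower, at 53.1 ± 12.2 CPM (-1.20 ± 0.20), and PISD, a mitochondrial phospholipid enzyme, 1.85-fold lower (-0.89 ± 0.14), each with edgeR adjusted p = 0.0326. The only gene called higher, the unnamed transcript RP11-196G18.24 (1.05 ± 0.17, edgeR adjusted p = 0.0326), is given because 5 genes passed in all and was chosen after its values were seen. RGS2 lies on chromosome 1 from 192809039 to 192812283 and PISD on 22 from 31618491 to 31662432 in GRCh38.

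The receptor genes did not pass under enzalutamide. ESR1 was at 234 ± 53.9 CPM (0.33 ± 0.18, edgeR adjusted p = 0.598), PGR at 227 ± 153 (-0.12 ± 0.44, 0.962), GREB1 at 385 ± 187 (-0.30 ± 0.36, 0.847) and MKI67 at 459 ± 27.3 (0.15 ± 0.19, 0.859). With no named gene passing as higher, those with the smallest p were NUDT9 (0.53 ± 0.11), C4orf32 (0.59 ± 0.12) and the mitochondrially encoded MT-ND3 (0.56 ± 0.13), with edgeR adjusted p of 0.167, 0.23 and 0.304.

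Androgen-response genes were lower on average under enzalutamide, at -0.44 over 39 genes (camera adjusted p = 5.5e-07, and adjusted p = 0.042 with an estimated correlation). SEC14L2 and FKBP5 passed, and 7 genes passed adjusted over the list alone, all lower. Apocrine and milk secretory genes had a mean of -0.88 over 14 genes (camera adjusted p = 1.3e-09, and adjusted p = 0.038 with an estimated correlation), with PIP at -1.53 ± 0.29 and TAT, a tyrosine-degrading enzyme, at -3.20 ± 0.84. In that list edgeR called 0, with 6 lower at an unadjusted p under 0.05 and 5 lower adjusted over the list alone, DESeq2 called 2 lower and limma-voom 0. The estrogen-response mean was -0.33, with 0 of 52 called by edgeR, DESeq2 or limma-voom, 0 adjusted over the list alone and 5 lower at an unadjusted p under 0.05 (camera adjusted p = 2.7e-06, and adjusted p = 0.61 with an estimated correlation). It was -0.20, -0.57 and -0.18 without Enzalutamide 1, 2 and 3. The tumours were split, with estrogen-response scores of 0.878 and 0.668 in Enzalutamide 2 and 4, within the vehicle libraries (0.577 to 0.913). Enzalutamide 1 and 3 lay below them, at -0.177 and -0.389. Mitochondrially encoded genes averaged 0.27, with 0 of 15 called by edgeR and limma-voom, 2 higher by DESeq2, 7 higher at an unadjusted p under 0.05 and 6 higher adjusted over the list alone (camera adjusted p = 7.9e-08, and adjusted p = 0.30 with an estimated correlation), and 0.15 without Enzalutamide 4.

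Further lists passed the camera test under enzalutamide with 0 members called by edgeR, DESeq2 or limma-voom and 0 adjusted over the list alone. Cholesterol synthesis had a mean of -0.19, with 4 of 22 genes lower at an unadjusted p under 0.05 (camera adjusted p = 0.0046, adjusted p = 0.81 with an estimated correlation), and was at -0.13 without Enzalutamide 4, where it missed the threshold. Fatty acid synthesis had a mean of -0.19, with 3 of 24 lower at an unadjusted p under 0.05 (camera adjusted p = 0.035, adjusted p = 0.47 with an estimated correlation), and missed the threshold at -0.14 without Enzalutamide 3, -0.18 without Enzalutamide 4 and -0.14 without Vehicle 4. Hypoxia genes had a mean of -0.54, with SLC2A1 at -0.79 ± 0.24 and 3 of 30 lower at an unadjusted p under 0.05 (camera adjusted p = 0.0029, adjusted p = 0.88 with an estimated correlation). That mean was -0.07 without Vehicle 2, -0.38 without Enzalutamide 1 and -0.39 without Enzalutamide 3, none of which passed, and -0.81 without Enzalutamide 4. Cell cycle inhibitors and DNA damage response genes had a mean of 0.13, with BTG2 at 0.40 ± 0.15 and 2 of 27 higher at an unadjusted p under 0.05 (camera adjusted p = 0.014, adjusted p = 0.47 with an estimated correlation), and missed the threshold at 0.11 without Enzalutamide 2 and 0.12 without Vehicle 1.

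S phase and G2/M genes had means of 0.00 and 0.03 under enzalutamide (camera adjusted p = 0.71 and 0.39), and without Vehicle 4 the G2/M mean was 0.12 (camera adjusted p = 0.0066). None of the other lists passed. Their means were -0.37 for steroid inactivation and synthesis, 0.02 for fatty acid oxidation, 0.03 for luminal receptors, -0.26 for interferon-stimulated genes and -0.03 for antigen presentation. They were -0.05 for the unfolded protein response, -0.07 for ribosome biogenesis, -0.12 for growth factor signalling, -0.08 for WNT signalling and -0.16 for immediate early genes. Ribosome biogenesis passed without Vehicle 2 (-0.10, camera adjusted p = 0.013) or Enzalutamide 4 (-0.12, camera adjusted p = 0.028). Markers of other cell types averaged 0.08 for fibroblasts, -0.19 for endothelium, -0.27 for leukocytes, -0.36 for adipocytes and -0.13 for basal and epidermal cells. Over the 24 lists with no called member, which hold 547 genes, edgeR called 0, 65 had an unadjusted p under 0.05, DESeq2 called 4 and limma-voom 0. The adipocyte median was 0.03, the fatty acid oxidation median -0.01 and the unfolded protein response median 0.00, against means of -0.36, 0.02 and -0.05.

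Between enzalutamide and vehicle edgeR called 5 genes, 1 higher and 4 lower, with 1532 at an unadjusted p under 0.05, while DESeq2 called 68 and limma-voom 0. Without Vehicle 1, Vehicle 3, Enzalutamide 1, Enzalutamide 3 or Enzalutamide 4 the count was 1, without Vehicle 4 it was 2 and without Enzalutamide 2 it was 13. RGS2 passed without any 1 library. SEC14L2 (-1.70 to -1.31), FKBP5 (-1.33 to -1.03) and PISD (-0.95 to -0.81) lost their calls without each of those libraries other than Enzalutamide 2 (adjusted p up to 0.19), and RP11-196G18.24 (0.97 to 1.10) without those or Vehicle 2.

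DHT and enobosarm were also compared directly, as a steroidal and a non-steroidal agonist given for the same 5 days by different routes and with no dose stated for DHT. Estrogen-response genes were lower under DHT, while the androgen-response list did not differ by its test. ESR1 was 3.38-fold lower under DHT (-1.76 ± 0.17, edgeR adjusted p = 5.02e-05) and GREB1 3.41-fold lower (-1.77 ± 0.35, edgeR adjusted p = 0.00893). PGR was 3.10-fold lower (-1.63 ± 0.43, edgeR adjusted p = 0.0439), a call that ended without any of DHT 2 to 5 or Enobosarm 1 to 4 (-1.77 to -1.40 over all left-out libraries, adjusted p up to 0.11). SEC14L2 was 2.33-fold lower under DHT (-1.22 ± 0.20, edgeR adjusted p = 0.00169). FKBP5 differed by 0.12 ± 0.18 (95% interval -0.26 to 0.51, edgeR adjusted p = 0.782), and MKI67 by 0.40 ± 0.19 (0.01 to 0.79, edgeR adjusted p = 0.264).

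Of 52 estrogen-response genes 30 were lower under DHT than under enobosarm and 0 higher by edgeR (38 and 0 adjusted over the list alone), with a mean difference of -1.34 (camera adjusted p = 3.1e-42, and adjusted p = 0.017 with an estimated correlation). BCL2, an inhibitor of apoptosis (-2.31 ± 0.23), MYB (-1.22 ± 0.14), RERG (-1.26 ± 0.16) and MAPT (-0.97 ± 0.14) had the smallest p-values. Of 39 androgen-response genes 1 was higher and 2 were lower (5 and 3 adjusted over the list alone), the lower ones SEC14L2 and ARSG (-0.90 ± 0.16), with a mean difference of 0.17 (camera adjusted p = 0.082). That list passed without DHT 1 (0.22, adjusted p = 0.0099), DHT 5 (0.17, adjusted p = 0.041) or Enobosarm 2 (0.27, adjusted p = 0.039), and its mean was 0.092 without Enobosarm 3 (adjusted p = 0.29) and 0.127 without DHT 2 (adjusted p = 0.3). It was -0.018 without the low-count filter (adjusted p = 0.11). Steroid inactivation and synthesis genes were higher under DHT, 4 of 17 and 0 lower by edgeR (8 and 2 adjusted over the list alone), with UGT2B28 at 2.27 ± 0.44 and HSD11B2 at 1.15 ± 0.22 (mean 0.50, camera adjusted p = 0.00053, and adjusted p = 0.023 with an estimated correlation). S phase genes averaged 0.19 (0 of 50 called by edgeR, 0 adjusted over the list alone, 4 higher at an unadjusted p under 0.05, DESeq2 1 and limma-voom 0, camera adjusted p = 0.00061, and adjusted p = 0.88 with an estimated correlation), and 0.02 without DHT 1. G2/M genes averaged 0.18 (0 of 48 called by edgeR, DESeq2 or limma-voom, 0 adjusted over the list alone, 4 higher at an unadjusted p under 0.05, camera adjusted p = 0.013, and adjusted p = 0.93 with an estimated correlation). The G2/M mean was -0.05 without DHT 1, 0.12, 0.16 and 0.15 without Enobosarm 1, 2 and 4, none of which passed, and 0.30 without Enobosarm 3.

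**Figure D2:**
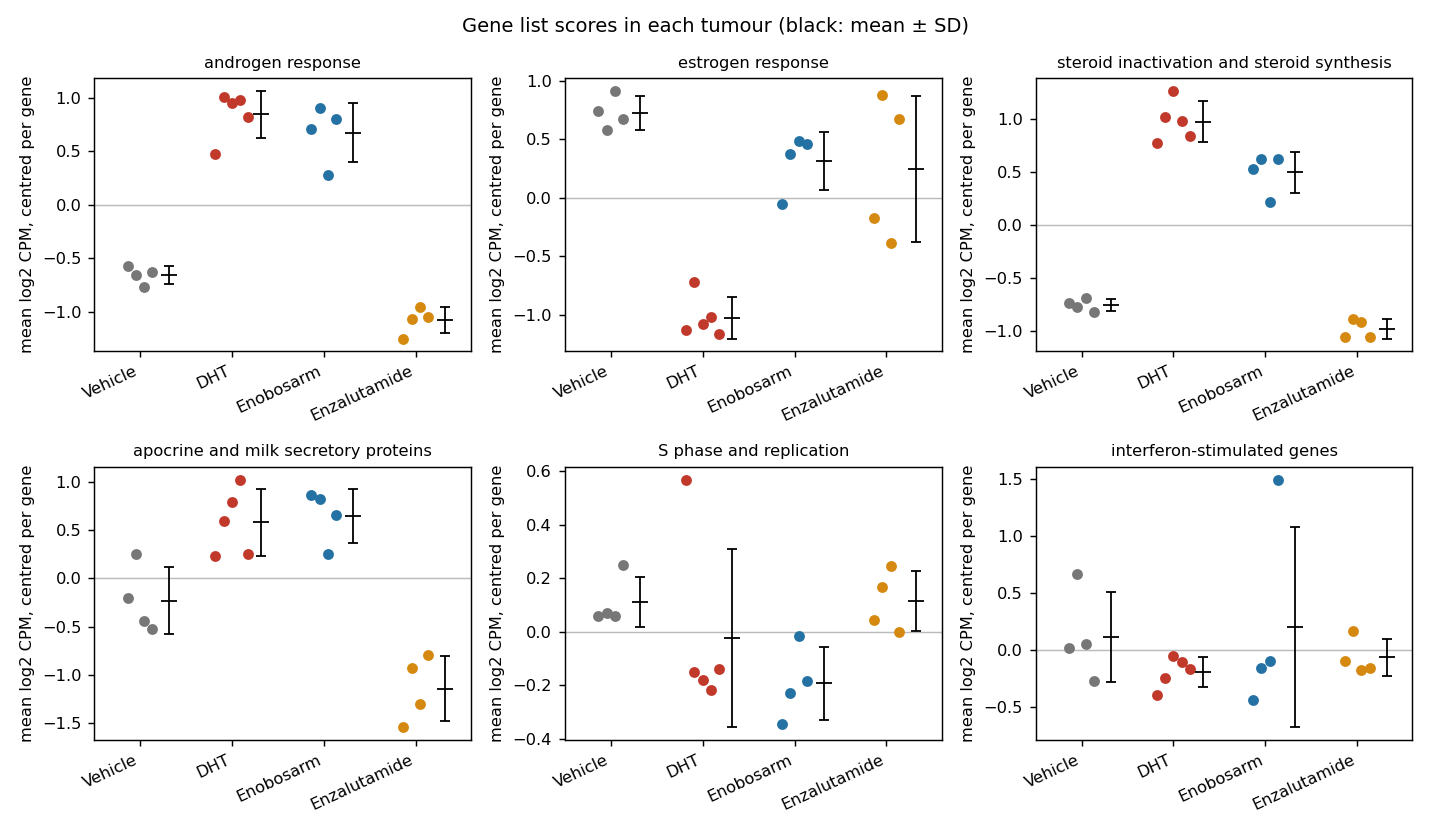
Score of 6 gene lists in each tumour, as the mean over a list of log2 CPM minus each gene's mean over the 17 tumours, with 1 point per tumour and the mean ± SD of each group in black. DHT 1 stands at 0.57 on the S phase list, with the other DHT tumours between -0.22 and -0.14, and Enobosarm 4 at 1.499 on the interferon list, with the other enobosarm tumours between -0.45 and -0.10.

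Genes with the largest differences that were higher under DHT than under enobosarm were the matrix genes TNC (3.61 ± 0.84) and SPARC (2.45 ± 0.62), UGT2B11 (2.35 ± 0.34), the adhesion molecule L1CAM (2.35 ± 0.51) and the alcohol dehydrogenase ADH1C (2.27 ± 0.32). Those lower under DHT were the potassium channel KCNH1 (-5.27 ± 0.81), the gap junction protein GJA1 (-4.78 ± 0.68), MAG, PDZK1 (-4.60 ± 0.76), which is in the estrogen-response list, and MAT1A (-4.54 ± 1.02). MAG had 1 to 3 counts under DHT and an enobosarm-to-DHT ratio with a 95% counting interval of 10.7 to 160. edgeR adjusted p for these 10 genes ranged from 0.000766 for ADH1C to 0.0312 for SPARC. TNC lost its call without DHT 5 (2.39, adjusted p = 0.053), Enobosarm 1, 3 or 4. SPARC (2.00 to 2.86) lost it without DHT 2, 3 or 5 or any 1 enobosarm library, and MAT1A (-5.17 to -3.85) without DHT 3, DHT 5 or Enobosarm 3.

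In the other lists, hypoxia genes averaged 0.42 higher under DHT (0 of 30 called by edgeR, DESeq2 or limma-voom, 0 adjusted over the list alone, 1 at an unadjusted p under 0.05, camera adjusted p = 0.014, and adjusted p = 0.92 with an estimated correlation). Their mean was 0.08 without DHT 2, 0.37 without DHT 4, 0.29 without Enobosarm 2 and 0.31 without Enobosarm 4, none of which passed, and 0.63 without Enobosarm 3. Fatty acid oxidation averaged 0.16 (1 of 19 higher, CPT1A at 0.70 ± 0.13, 1 adjusted over the list alone, camera adjusted p = 0.036, and adjusted p = 0.61 with an estimated correlation), and missed the threshold at 0.13, 0.16, 0.14 and 0.13 without DHT 1, DHT 2, Enobosarm 1 and Enobosarm 4. Interferon-stimulated genes averaged -0.78 (2 of 24 lower, 3 adjusted over the list alone, camera adjusted p = 0.05), with ISG15 at -2.91 ± 0.79 and IFI6 at -2.93 ± 0.79. Without Enobosarm 4 the mean was 0.06, ISG15 was at -1.12 (adjusted p = 0.38) and IFI6 at -1.29 (adjusted p = 0.31), and both genes also missed the threshold without Enobosarm 3 or any 1 DHT library. The list passed without DHT 3 (-0.82), DHT 5 (-0.78), Enobosarm 1 (-0.95), Enobosarm 2 (-0.91) or Enobosarm 3 (-0.91), with camera adjusted p from 0.0014 to 0.048. In the growth factor list 3 of 32 were lower (1 higher and 6 lower adjusted over the list alone), including IGF1R (-1.75 ± 0.22). In the WNT list 1 of 19 was higher and 2 lower (2 and 4 adjusted over the list alone), including JAG1 (-2.40 ± 0.34). In the luminal list 4 of 28 were lower (5 higher and 4 lower adjusted over the list alone), with GATA3 at -1.05 ± 0.18. MYC (-0.98 ± 0.18), EGR3 (-3.27 ± 0.58) and KRT14 (-2.20 ± 0.43) were lower under DHT. Their lists held 1 lower of 29 for ribosome biogenesis (1 adjusted over the list alone), 2 lower of 28 for immediate early genes (2 higher and 2 lower adjusted over the list alone) and 2 higher and 1 lower of 10 for basal and epidermal markers (4 and 1 adjusted over the list alone).

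The unfolded protein response list held 1 higher and 1 lower of 26 between DHT and enobosarm (2 and 1 adjusted over the list alone), and cholesterol synthesis 1 higher of 22 (2 adjusted over the list alone), HMGCS1 at 0.41 ± 0.09. There was 1 gene higher among fibroblast markers, SPARC, of 14 (1 higher and 1 lower adjusted over the list alone), and 1 lower of 6 among endothelial and pericyte markers (1 adjusted over the list alone). Neither these nor the growth factor, WNT, luminal, ribosome biogenesis, immediate early and basal lists passed the camera test. Ribosome biogenesis passed without DHT 1 (-0.15 against -0.07, camera adjusted p = 0.016), cholesterol synthesis without Enobosarm 3 (0.15 against 0.06, camera adjusted p = 0.026), and basal and epidermal markers without DHT 4 (0.63 against 0.48, camera adjusted p = 0.01) or Enobosarm 3 (0.58, camera adjusted p = 0.048). Luminal, immediate early, apocrine and endothelial lists had means of -0.06, -0.07, -0.03 and -0.16 and medians of 0.13, 0.09, 0.07 and 0.11. Across the 10 lists with no called member, including fatty acid synthesis, apocrine, cell cycle inhibitor, antigen presentation, mitochondrially encoded, leukocyte and adipocyte genes, edgeR called 0 of 235 genes, 18 had an unadjusted p under 0.05, DESeq2 called 3 and limma-voom 0.

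Between DHT and enobosarm edgeR called 679 genes, 222 higher and 457 lower under DHT, of which 82 and 301 differed at least 2-fold. DESeq2 called 1197, 520 higher and 677 lower, and limma on log2(TPM + 1) 376. The edgeR count was 447 without DHT 3, 412 without DHT 5, 323 without Enobosarm 3 and 362 without Enobosarm 4.

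Across genes, the responses to DHT and to enobosarm ran in parallel. Their log2 fold changes against vehicle had a Pearson correlation of 0.765 and a Spearman correlation of 0.698 over 16780 genes, which are not independent replicates. Because both use the same 4 vehicle libraries, 100 simulations of unchanged groups against those libraries gave a mean correlation of 0.518 and a maximum of 0.559. The covariance was 0.414 against 0.049 simulated, a difference of 0.365. With the vehicle libraries split 2 against 2 the correlation was 0.555 to 0.68 over 6 arrangements. Both comparisons called 862 genes higher and 578 lower, where independent lists would share 128 and 93.7. The split vehicle libraries, with fewer calls, gave 309 to 488 and 106 to 258. Independent lists in those arrangements would share 31.4 to 61.5 and 14.4 to 49.2. PIGT (-0.41 under DHT and 0.47 under enobosarm), SPOCD1 (-1.26 and 1.54) and PCSK1 (-1.81 and 1.55) were called in opposite directions. They are the only 3 such genes and were chosen after their values were seen. Their edgeR adjusted p ranged from 0.0157 to 0.0364, near the threshold, so false calls among them are not excluded.

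**Figure D3:**
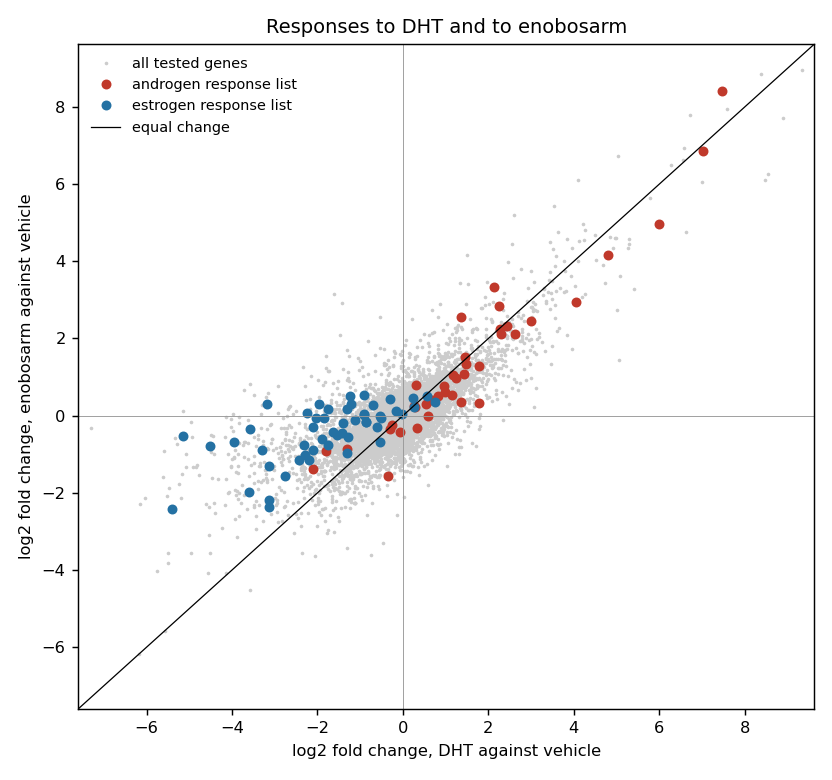
Log2 fold change against vehicle under DHT (horizontal axis) and under enobosarm (vertical axis) for 16780 genes in grey, with the androgen-response list in red, the estrogen-response list in blue and the line of equal change in black. The androgen-response list averaged 1.54 under DHT and 1.38 under enobosarm, and the estrogen-response list -1.75 and -0.41.

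The antagonist was also set against each agonist. FKBP5 was 12.6-fold higher under DHT than under enzalutamide (3.65 ± 0.21, edgeR adjusted p = 7.72e-09) and SEC14L2 12.7-fold higher (3.67 ± 0.24, edgeR adjusted p = 2.60e-08), while ESR1 was 7.59-fold lower (-2.92 ± 0.18, edgeR adjusted p = 1.29e-08). PGR (-3.50 ± 0.45) and GREB1 (-1.53 ± 0.35) were also lower under DHT, with edgeR adjusted p of 4.46e-05 and 0.00429, and MKI67 differed by -0.05 ± 0.18 (edgeR adjusted p = 0.871). Under enobosarm FKBP5 was 11.5-fold (3.53 ± 0.21, edgeR adjusted p = 9.87e-09) and SEC14L2 29.6-fold (4.89 ± 0.25, edgeR adjusted p = 3.09e-09) higher than under enzalutamide. ESR1 was 2.25-fold lower (-1.17 ± 0.18, edgeR adjusted p = 0.000325), with PGR at -1.86 ± 0.45, GREB1 at 0.24 ± 0.36 and MKI67 at -0.45 ± 0.19 (edgeR adjusted p = 0.0136, 0.735 and 0.146). RGS2 was 23.7-fold higher under DHT and 42.0-fold higher under enobosarm than under enzalutamide (4.57 ± 0.26 and 5.39 ± 0.27). edgeR called 3852 genes between DHT and enzalutamide (1995 higher and 1857 lower) and 2076 between enobosarm and enzalutamide (1237 higher and 839 lower).

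Androgen-response genes averaged 1.98 higher under DHT and 1.82 higher under enobosarm than under enzalutamide, with 26 and 24 of 39 higher (28 and 26 adjusted over the list alone; camera adjusted p = 7.4e-29 and 4.7e-32). The estrogen-response mean was -1.42 for DHT, with 34 of 52 lower (37 adjusted over the list alone, camera adjusted p = 8.1e-18, and adjusted p = 0.15 with an estimated correlation), and -0.08 for enobosarm, with 10 lower (10 adjusted over the list alone, camera adjusted p = 0.84) and a median of 0.001. Apocrine and milk secretory genes averaged 1.79 and 1.82, with 9 and 9 of 14 higher (9 and 11 adjusted over the list alone; camera adjusted p = 1.5e-12 and 1.9e-17). The genes called in opposite directions against vehicle were FKBP5, SEC14L2 and RGS2 for DHT and enzalutamide, and those 3 and PISD for enobosarm and enzalutamide. The log2 fold changes of enzalutamide correlated across genes at 0.193 with those of DHT and 0.131 with those of enobosarm, where unchanged groups sharing the vehicle libraries gave means of 0.506 and 0.482. The covariances were 0.062 and 0.033 against 0.049 simulated, and the correlations -0.041 to 0.166 and -0.113 to 0.087 with the vehicle libraries split.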

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

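The tests of how often other groupings of the libraries call as many genes were set before their results were seen, and the tests of depth, labels and response size were chosen only after the result was seen. The groupings were 100 drawn from a larger number, the real one included, for comparisons of 5 with 4 libraries, and all 35 for 4 with 4. For each comparison other than enzalutamide against vehicle, the other groupings that were run called fewer genes than the real one. That argues against chance in the grouping as the source of these counts. It does not exclude chance, since 1 of 35 and 1 of 100 are the smallest shares that these groupings can give. The real grouping was the 1 of 100 with as many genes for DHT against vehicle (4202, highest other 3374), 1 of 35 for enobosarm against vehicle (1769, highest other 1), 1 of 100 for DHT against enobosarm (679, highest other 415), 1 of 100 for DHT against enzalutamide (3852, highest other 2987) and 1 of 35 for enobosarm against enzalutamide (2076, highest other 29). The other groupings with 3374 and 2987 genes placed DHT 1 with the opposite group, and the one with 415 placed DHT 2 there, with the remaining DHT libraries together, so they still hold most of the real difference. For enzalutamide against vehicle the real grouping was also the 1 of 35, the smallest share that 35 groupings can give, but with 5 genes against 3 for the highest other. That count fell to 0 with only the 2 groups compared, with limma-voom and with thinned libraries, so the grouping test is weak evidence against chance there.

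DHT 1 stood apart from the other DHT tumours, by the rule for single libraries in cell-cycle genes, with an S phase score of 0.569 (others -0.218 to -0.14) and a G2/M score of 0.671 (others -0.349 to -0.187). It also lay outside the other DHT libraries without being marked in other values, among them mitochondrially encoded genes at 0.326 (others -0.178 to 0.014), ribosome biogenesis and MYC target genes at 0.169 (others -0.325 to -0.071), androgen-response genes at 0.476 (others 0.819 to 1.012) and a score of -49.8 on PC3, a principal component of log2 CPM (others -7.6 to 13.8). On any score some library of a group must lie outermost, and these values were chosen after they were seen, so they are no further evidence. The 15 leukocyte marker genes of DHT 1 summed to 28.1 CPM, the highest of the 17 libraries (other DHT 8.66 to 15.4), of which S100A9 gave 16.57 CPM (other DHT 2.29 to 6.41). Its library is the smallest. With the others thinned to its total the S phase gap was 0.706, against 0.709 before and a range of 0.074 among the others. That argues against a counting effect of its low total. Thinning keeps each gene's expected share of the counts, so library or RNA quality was not tested. A vehicle or enzalutamide tumour under this label is argued against by its androgen-response score, 1.047 above the highest of those libraries (their range 0.681), and an enobosarm tumour by its estrogen-response score, 1.081 below the lowest of those (their range 0.533). The library number of DHT 1 is 12, among enzalutamide and enobosarm libraries numbered 10 to 14. The other DHT libraries are numbered 17, 18, 25 and 26, next to vehicle libraries. Whether these numbers mark an order of processing is not known, and their part in the scores of DHT 1 was not tested. A swap with a tumour from outside the series and a share of other cell types were not tested, and no biological explanation was tested, so what sets this tumour apart stays open.

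Vehicle 4 had an S phase score of 0.251 (other vehicle libraries 0.06 to 0.068). Enobosarm 3 had a fatty acid synthesis score of 0.405 (others 0.152 to 0.188) and a leukocyte marker score of 0.44 (others -0.369 to -0.233). DHT 2 had an immediate early and heat-shock score of 0.551 (others -0.12 to -0.057). Vehicle 2 had a fibroblast marker score of -0.582 (others 0.163 to 0.2). Each was marked by its gap to the nearest library of its group, relative to the group's range. Of 132 groups of scores checked, 7 held such a library, where chance gives about 6.6.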

How the results depend on the processing

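Thinning every library to the smallest total was chosen only after the data were seen, and the other alternatives were set before. Counts of called genes for DHT against vehicle (3174 to 4670), DHT against enzalutamide (2896 to 4301) and enobosarm against enzalutamide (1418 to 2643) stayed within 1.5 times the reported counts in every alternative, and leaving out 1 library gave 3248 to 4610, 3006 to 4191 and 1527 to 1877. For enobosarm against vehicle only leaving out a library did more, with 1073 to 1684. The 5 genes of enzalutamide against vehicle became 3 with the replicate block, 1 with library number as covariate, 0 with libraries thinned to equal totals, 0 with only the 2 groups compared, 68 with DESeq2, 0 with limma-voom, 1 with limma on log2(TPM + 1) and 1 to 13 without 1 library, against 1532 at an unadjusted p under 0.05 in edgeR. The 679 genes of DHT against enobosarm became 260 with the replicate block, 1197 with DESeq2, 376 with limma on log2(TPM + 1) and 323 to 770 without 1 library. The cause of these changes was not tested. Same-numbered libraries did not in general deviate together (24 pairs over 5000 genes, r from -0.585 to 0.272, 8 above 0.1). Of the libraries with a same-numbered partner 0 correlated best with it. Expression thus gave no sign of pairing by number, but this cannot show whether the numbers mark a shared day, cage or batch. The correlation of the DHT and enobosarm responses was 0.838 over genes called in either comparison, 0.624 with the vehicle libraries split 2 against 2 and 0.723 to 0.788 without 1 library. At an adjusted p under 0.01, 96% of the authors' matched genes were also called.

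Among the 4 leading lists, camera with an estimated correlation and fry kept the means but not the calls of G2/M for DHT against vehicle (-0.204, adjusted p = 0.97 and 0.48), estrogen response (-0.414, 0.86 and 0.24), S phase (-0.307, 0.86 and 0.18) and G2/M (-0.381, 0.86 and 0.22) for enobosarm against vehicle, estrogen response for enzalutamide against vehicle (-0.332, 0.61 and 0.24), and S phase (0.193, 0.88 and 0.42) and G2/M (0.177, 0.93 and 0.63) for DHT against enobosarm. An estimated correlation widens the test where the genes of a list vary together. G2/M for DHT against vehicle also missed the threshold with only the 2 groups compared (-0.196) and the replicate block (-0.17), and androgen response for DHT against enobosarm passed with the replicate block (0.153). Without 1 library the means ranged from -0.279 to -0.062 (S phase) and -0.427 to -0.117 (G2/M) for DHT against vehicle, and from -0.025 to 0.118 (G2/M) for enzalutamide against vehicle. For DHT against enobosarm they ranged from 0.092 to 0.272 (androgen response), 0.021 to 0.263 (S phase) and -0.054 to 0.297 (G2/M), the last changing sign without DHT 1. Of the values of named genes under the alternatives, 5725 stayed on their side of the threshold, 101 passed it and 309 no longer passed. Among these, 0 called values changed direction, and values called in neither setting were not checked for direction. Of the values of the other lists, 2176 stayed on their side of the threshold, 66 passed and 103 no longer passed. With totals from 8495428 counts, genes at a few counts carry little information.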

Other observations

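The tests in this part were all chosen only after the result was seen. Estrogen-response genes were lower under DHT than under enobosarm. With every library thinned to the smallest total the mean difference was -1.335 (unthinned -1.339), which argues against a counting effect of uneven depth. Thinning keeps each gene's expected share of the counts, so differences in library or RNA quality were not tested. If enobosarm acted as a weaker dose of the same agonist on every list, its mean change relative to DHT would be alike in both lists. That ratio was 0.886 ± 0.107 for androgen-response and 0.234 ± 0.078 for estrogen-response genes, a difference of 0.652 ± 0.123 (jackknife SE over 13 libraries), which argues against 1 common ratio. A list that responds at lower doses could still saturate first, so the dose, the route and the compound remain open, and they differ together between these groups.

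Enobosarm 4 was noticed by eye for its interferon score of 1.499 (other enobosarm libraries -0.446 to -0.103), and the rule for single libraries did not mark it. With every library thinned its gap to the next was 1.548, against 1.602 before and a range of 0.304 among the others. That argues against a counting effect of depth, while library or RNA quality was not tested. Its 30 interferon-stimulated genes summed to 735 CPM, against 347 to 393 in the other enobosarm libraries. Its 15 leukocyte marker genes summed to 9.52 CPM, within the other enobosarm libraries (7.77 to 16.6). LYZ among them was at 3 CPM against 1 to 1.6, and PTPRC at 0.051 CPM against 0 to 0.056. A human cell line grown in mice gives no source of human leukocytes and the markers are near the floor, so this sum decides nothing about leukocytes. Mouse leukocytes were not tested, and no biological explanation was tested.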
